A study of Mus musculus with 6 samples.

How the data were processed

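RNA was measured in 6 libraries of cultured neonatal mouse microglia, 3 from Plcg2+/+ and 3 from Plcg2-/- littermates of the C57BL/6 strain. Per the labels' protocols, mixed glial cultures were made from forebrains of pups aged 2 to 3 days in medium with 10% serum and 5 ng/mL GM-CSF, RNA was taken from the microglia with a column kit and DNase, and polyA-selected libraries were read as 150-bp paired ends, with about 20 M reads per sample stated. Genotype and replicate number come from the sample titles. The labels do not say that each replicate is a separate animal or culture, so p-values measure only the spread between these samples, which may be technical.

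The authors deposited 1 table of TPM per gene, with 54347 gene rows and a column per sample; each column sums to 1000000, so TPM keeps no depth and the depth behind a value cannot be read from it. Per the submitters' processing notes, Salmon 1.3.0, DESeq2 1.30.1 and R 4.0.4 were used with the build GRCm38.p6; the annotation release and the step that produced the TPM values are not given in the sources used here. Counts were not analysed here, so no count model was fitted. Of the rows, 54094 had an identifier in GENCODE M21 (GRCm38), which gave positions and gene types; 102 symbols stood on more than 1 row and were kept apart.

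TPM values were put on the log2(TPM + 1) scale with no further scaling, which understates the change of genes with low values. The 12652 genes with a mean TPM of at least 1 over the 6 samples were tested, 11040 of them protein coding, between the 2 genotypes with limma 3.58.1 in R 4.3.3 (two-sided moderated test, mean-dependent prior variance, 4 residual and 2.97 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p below 0.05 was the threshold. Standard errors are the moderated ones; ± after a TPM mean is the SD. The table was read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

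The 39 gene lists (846 genes, all found in the table) were fixed from general knowledge before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 35 lists, and beside it with an estimated correlation and with fry. The setting of camera that lets the prior variance follow the mean, to match the gene test, was chosen after a first run with the default; 13 lists passed either way. The rule for named genes, also fixed beforehand, took Plcg2, the 12 highest and 12 lowest log2 fold changes among called genes with a mean TPM of at least 5 whose 3 values in one genotype all lay above the 3 of the other (predicted genes and sex-linked genes left out), up to 4 members per list with the smallest p, and any member of the endocannabinoid and eicosanoid synthesis lists. Shares of TPM were compared by exact permutation tests, two-sided, for which 0.1 is the smallest p with 3 against 3.

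Replicate numbers 1 to 3 occur in both genotypes and come from the titles. Deviations from the genotype means, over the tested genes, correlated at 0.295, 0.193 and 0.147 between libraries with the same number and at most 0.00369 between libraries with different numbers. Deviations cancel within a genotype for each gene, so positive values for same numbers force lower ones for different numbers. The low values are therefore not separate support for pairing. All 3 were above 0.1, the limit set beforehand, so the numbers were taken to pair the samples. The main fit still had no block, since the labels do not say that a number marks a litter. P-values given here are unpaired unless the block is named. Counts of a fit with the pairs as a block had been seen in the same output as the correlations. That fit called 2483 genes higher and 815 lower, 2501 of its calls being shared with the fit without the block.

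The gene test was checked on simulated data, in which 200 of 12652 simulated genes were changed by known sizes for 3 against 3 libraries. The variance of each gene within genotypes was averaged with the median variance of all genes. Values were drawn independently for each gene and library, without correlation between genes or pairing of libraries. Of changed genes with a mean TPM of at least 5, 0 of 39 were recovered at a log2 size of 0.5, 26 of 36 (72.2%) at 1, 35 of 35 at 2 and 37 of 38 (97.4%) at 3, and 5 of 136 calls (3.68%) were false. With no gene changed there were 0 calls. Since the simulation left out pairing and correlation between genes, these rates may not hold for the real libraries. It also changed only 200 genes and gave 136 calls, against 2643 calls in the real libraries. With fewer calls the Benjamini-Hochberg cut-off is stricter, so the recovery of small changes may be understated. Settings tried beside the main ones were pseudocounts of 0.1 and 0.5, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, constant and robust prior variances, sample weights, the replicate block, a covariate for the summed level of 4 Y-linked genes, leaving out each library, other thresholds and other list tests. Added after the data were seen were rescaling without mitochondrially encoded genes, scaling without the 100 most abundant genes, the block together with median-of-ratios scaling, and leaving out both libraries numbered 1.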

Results

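The data are messenger RNA levels of primary microglia, the resident macrophages of the brain, grown from forebrains of newborn C57BL/6 mice. Pups were 2 to 3 days old. Microglia were shaken off mixed glial cultures on day 12 to 13 and rested for at least 72 h in medium with 1% serum and 0.5 ng/mL GM-CSF, a myeloid growth factor. The 6 libraries comprise 3 from Plcg2+/+ and 3 from Plcg2-/- littermates, and single libraries are named here by genotype and replicate number, as in Plcg2+/+ 1. Values are TPM, transcript abundances scaled to the same total in each library, which carry no depth, so the depth behind each value is unknown here. Between 20102 and 21598 genes were above 0 in each library. Across genes, the correlation of log2(TPM + 1) between libraries was 0.953 to 0.966 within a genotype and 0.894 to 0.938 between genotypes; genes are not independent replicates. The first principal component held 51.9% of the variance and separated the genotypes.

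Plcg2 encodes phospholipase C gamma 2, which cleaves a membrane phosphoinositide into diacylglycerol and inositol trisphosphate downstream of immune receptors. The gene (ENSMUSG00000034330.10) lies on GRCm38 chromosome 8, positions 117498291 to 117635142, plus strand, and is protein coding. Its level was 45.2, 39.7 and 54.9 TPM in the Plcg2+/+ libraries and 16.05, 16.7 and 16.1 TPM in the Plcg2-/- libraries. The mean was 46.6 ± 7.67 TPM (SD, n = 3) in Plcg2+/+ and 16.3 ± 0.374 TPM (SD, n = 3) in Plcg2-/-. Plcg2 fell by 1.45 ± 0.14 (SE) on the log2 scale (limma adjusted p = 0.00141). Transcript remained in the knockout libraries, and which part of the gene was removed is not given in the sources used here.

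The comparison of Plcg2-/- with Plcg2+/+ microglia asks which transcripts differ when phospholipase C gamma 2 is lost. Ccl8 and Cxcl10, which encode chemokines, had the largest increases among the genes taken by the rule: Ccl8 rose from 5.22 ± 1.55 to 319 ± 175 TPM (SD, n = 3 each), Cxcl10 from 2.92 ± 1.26 to 145 ± 46.9 and the chemokine gene Ccl12 from 4.26 ± 2.28 to 146 ± 44.5. The largest decrease among them was that of Eef1a2, a translation elongation factor gene, at -4.66 on the log2 scale. Mmp12, macrophage metalloelastase, fell from 14176 ± 3307 to 601 ± 166 TPM. Itgax, which encodes the integrin CD11c, fell from 273 ± 88.0 to 12.5 ± 4.82 TPM, and the secreted phosphoprotein gene Spp1 from 22732 ± 3104 to 2036 ± 1023. Their log2 fold changes, Plcg2-/- over Plcg2+/+ on the log2(TPM + 1) scale, were 5.53 ± 0.45 (SE), 5.23 ± 0.31, 4.88 ± 0.39, -4.57 ± 0.26, -4.36 ± 0.33 and -3.60 ± 0.37. The remaining 9 of the 12 strongest increases were Ly6a, Ms4a4c, Ifi205, Ifit1bl1, Tgtp2, Iigp1, Ifit2, Slfn1 and Apol7c, with log2 fold changes of 3.89 to 4.96. The remaining 9 of the 12 strongest decreases were Eef1a2, Dok7, Dcstamp, Mamdc2, Mfge8, Pdpn, Gpc1, Fn1 and Tmem178, at -4.66 to -3.38. Among these, Dcstamp is needed for macrophage fusion and Mfge8 bridges apoptotic cells to phagocytes. The highest limma adjusted p among the 24 genes was 0.00357. Members of the Ifit, Ifi, Ms4a, Slfn and Ccl families are close relatives, and whether reads were shared between them was not tested.

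Of 12652 genes tested, 1971 were higher and 672 lower in Plcg2-/- microglia at a limma adjusted p below 0.05, so 74.6% of the calls were increases. All 3 values of one genotype lay above all 3 of the other for 4097 higher and 1382 lower genes, 43.3% of those tested against 10% by chance. The split depended on scale. The median log2 fold change of all tested genes was 0.19 in the deposited TPM and -0.0045 after median-of-ratios scaling, where 975 genes were higher and 993 lower, 49.5% increases. Of the calls on deposited TPM, 975 increases and 671 decreases were also called after that scaling. Mitochondrially encoded transcripts took 15.5 ± 1.87% (SD, n = 3) of all TPM in Plcg2+/+ and 7.30 ± 2.01% (SD, n = 3) in Plcg2-/- libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Counts were 782 higher and 327 lower without Plcg2+/+ 1, 940 and 409 without Plcg2+/+ 2, 559 and 276 without Plcg2-/- 1, and 786 and 397 without Plcg2-/- 3.

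The series title names endocannabinoid and eicosanoid networks, and endocannabinoid genes moved both ways, as the plot of lipid genes per library shows. Daglb, which makes the endocannabinoid 2-arachidonoylglycerol from diacylglycerol, fell from 102 ± 34.1 to 30.8 ± 3.28 TPM (SD, n = 3 each), by 1.65 ± 0.24 (SE) on the log2 scale (limma adjusted p = 0.00581). Gde1, a phosphodiesterase that releases N-acylethanolamines, fell from 135 ± 1.42 to 79.0 ± 4.24 TPM (limma adjusted p = 0.00335). Gpr55, a receptor for lysophosphatidylinositol, rose from 1.29 ± 0.608 to 5.58 ± 0.917 TPM (limma adjusted p = 0.00687). Ddhd1, a phospholipase, rose from 105 ± 17.5 to 205 ± 32.6 TPM and the acylethanolamine hydrolase gene Naaa from 83.9 ± 49.9 to 297 ± 122 (limma adjusted p = 0.0131 and 0.0464). Mgll, the main 2-arachidonoylglycerol hydrolase, stood at 136 ± 2.52 TPM in Plcg2+/+ and 155 ± 36.1 TPM in Plcg2-/-. The cannabinoid receptor gene Cnr2 stood at 23.6 ± 0.734 TPM in Plcg2+/+ and 23.6 ± 6.09 TPM in Plcg2-/- (limma adjusted p = 0.509 and 0.922). Dagla, Abhd6 and Abhd12 did not pass either (limma adjusted p = 0.329, 0.464 and 0.397). Of 13 tested endocannabinoid genes, 3 were higher and 2 lower, against 3 and 2 adjusted over the list alone and 2 and 2 after median-of-ratios scaling. As a list they did not pass (camera adjusted p = 0.459). Endocannabinoid counts, higher and lower, were 1 and 2 without Plcg2-/- 1 and 1 and 2 without Plcg2-/- 3. Naaa had a limma adjusted p of 0.0636 after median-of-ratios scaling, 0.113 without Plcg2+/+ 1, 0.106 without Plcg2+/+ 2, 0.167 without Plcg2-/- 1 and 0.147 without Plcg2-/- 3. Ddhd1 had one of 0.067 without Plcg2-/- 1 and 0.0553 without Plcg2-/- 3. With the Y-linked level as a covariate Naaa also lost its call.

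Among genes of eicosanoid synthesis and inactivation, Tbxas1 and Ptgs1 fell and Hpgds, Hpgd and Ptges3 rose. Tbxas1, thromboxane synthase, fell from 87.1 ± 10.2 to 32.4 ± 5.19 TPM and Ptgs1, a cyclooxygenase, from 46.2 ± 3.00 to 20.4 ± 6.71 (SD, n = 3 each; limma adjusted p = 0.00213 and 0.0181). Hpgds, haematopoietic prostaglandin D synthase, rose from 41.6 ± 8.41 to 95.5 ± 13.2 TPM (limma adjusted p = 0.00670). Hpgd, a dehydrogenase that inactivates prostaglandins, rose from 61.8 ± 9.91 to 141 ± 29.2 TPM and Ptges3 from 52.4 ± 6.42 to 75.1 ± 3.46 (limma adjusted p = 0.00902 and 0.0272). Pla2g4a, the cytosolic phospholipase that releases arachidonate, did not pass at 22.0 ± 3.17 TPM in Plcg2+/+ and 33.9 ± 7.42 TPM in Plcg2-/- (limma adjusted p = 0.0717, 0.0285 without Plcg2-/- 2). Lta4h did not pass at 53.8 ± 7.38 TPM in Plcg2+/+ and 69.9 ± 10.6 TPM in Plcg2-/- (limma adjusted p = 0.133). With the replicate block both passed (limma adjusted p = 0.0173 and 0.0464). Ltc4s, leukotriene C synthase, had 255 ± 153 TPM in Plcg2+/+ and 102 ± 22.0 TPM in Plcg2-/- (limma adjusted p = 0.0994, 0.0335 without Plcg2+/+ 2). Alox5 and Alox5ap did not pass (limma adjusted p = 0.495 and 0.267). Of 16 tested eicosanoid synthesis genes, 3 were higher and 2 lower, against 3 and 2 adjusted over the list alone and 2 and 2 after median-of-ratios scaling. Eicosanoid synthesis genes counted 5 higher and 2 lower with the replicate block. The list did not pass (camera adjusted p = 0.672). Eicosanoid synthesis counts, higher and lower, were 2 and 1 without Plcg2+/+ 1 and 1 and 1 without Plcg2-/- 1. Ptgs1 had a limma adjusted p of 0.0617 without Plcg2+/+ 1, 0.0661 without Plcg2+/+ 2 and 0.0547 without Plcg2-/- 1, and Hpgd one of 0.0514 without Plcg2-/- 1. Ptges3 had one of 0.0721 after median-of-ratios scaling, 0.0828 without Plcg2+/+ 1, 0.0636 without Plcg2+/+ 2, 0.102 without Plcg2-/- 1 and 0.0905 without Plcg2-/- 3. With the Y-linked level as a covariate Ptgs1 and Ptges3 also lost their calls.

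Receptors of eicosanoids also moved both ways. The prostaglandin E receptor gene Ptger2 fell from 8.37 ± 0.830 to 3.40 ± 0.589 TPM and the cysteinyl leukotriene receptor gene Cysltr1 rose from 4.53 ± 1.52 to 11.8 ± 3.83 (SD, n = 3 each; limma adjusted p = 0.00569 and 0.0302). The eicosanoid receptor list also holds transporter genes, of which Abcc1 and Abcc4 were tested. Of its 8 tested genes, 1 was higher and 1 lower. Adjusted over the list alone the counts were 2 and 1, and after median-of-ratios scaling 0 and 1. They did not pass as a list (camera adjusted p = 0.310). Eicosanoid receptor counts, higher and lower, were 0 and 2 without Plcg2+/+ 2, 0 and 1 without Plcg2+/+ 3, 0 and 1 without Plcg2-/- 1, 2 and 1 without Plcg2-/- 2 and 0 and 1 without Plcg2-/- 3. Cysltr1 had a limma adjusted p of 0.0503 after median-of-ratios scaling, 0.0997 without Plcg2+/+ 2, 0.0651 without Plcg2+/+ 3, 0.124 without Plcg2-/- 1 and 0.105 without Plcg2-/- 3. With the Y-linked level as a covariate it also lost its call.

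**Figure D1:**
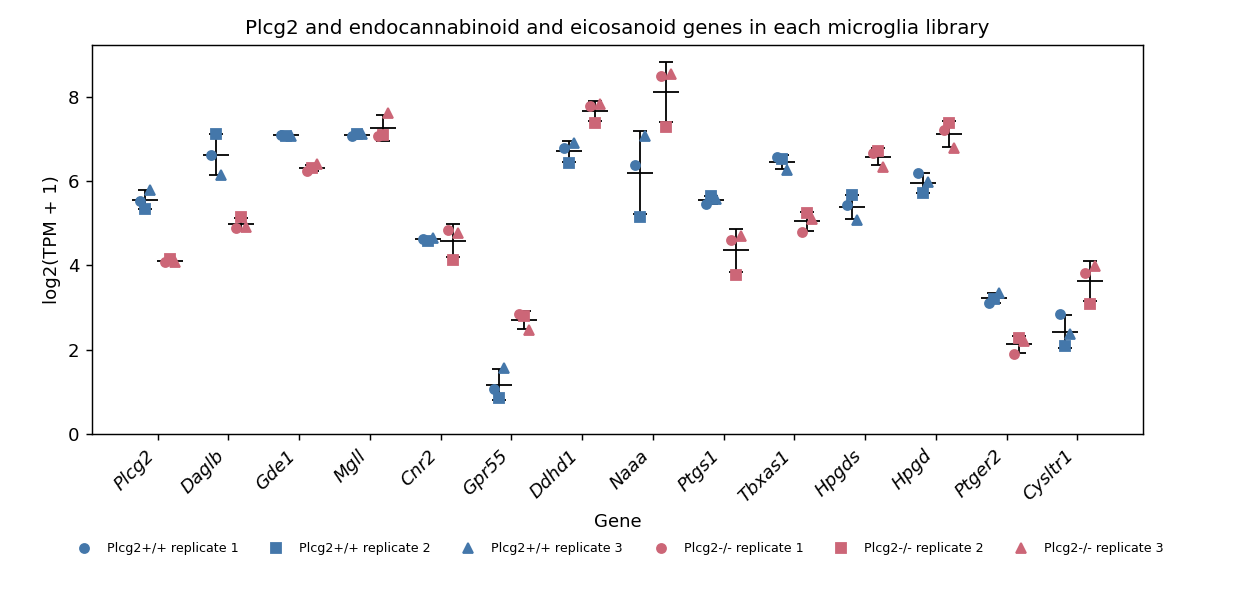
Log2(TPM + 1) of Plcg2 and of 13 endocannabinoid and eicosanoid genes in each of the 6 libraries, where symbols are single libraries, the black bar is the mean of 3 and whiskers are ± 1 SD. The Plcg2-/- libraries lie below all Plcg2+/+ libraries for Plcg2, Daglb, Gde1, Ptgs1, Tbxas1 and Ptger2, above them for Gpr55, Ddhd1, Naaa, Hpgds, Hpgd and Cysltr1, and overlap them for Mgll and Cnr2.

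In the ITAM receptor signalling list, which holds activating and inhibitory immune receptors, kinases, adaptors, phosphatases and a growth factor receptor, 13 of 31 genes rose and 2 fell. The activating Fc receptor gene Fcgr1 and the inhibitory Fc receptor gene Fcgr2b rose from 103 ± 4.75 to 259.6 ± 37.2 and from 96.8 ± 21.9 to 311 ± 34.6 TPM, and the lectin receptor gene Clec4n from 599 ± 113 to 1482 ± 44.0 TPM (SD, n = 3 each). Lat2, an adaptor of immune receptor signalling, fell from 181 ± 35.9 to 43.6 ± 1.24 TPM (highest limma adjusted p of the 4 genes = 0.00347). Trem2, a lipid-sensing microglial receptor singled out after its values were seen, fell from 1174 ± 332 to 364 ± 154 TPM (limma adjusted p = 0.0139, 0.0548 without Plcg2+/+ 1, 0.0636 without Plcg2-/- 1 and 0.0592 without Plcg2-/- 3). Of 31 tested ITAM receptor signalling genes, 13 were higher and 2 lower, against 20 and 2 adjusted over the list alone and 11 and 2 after median-of-ratios scaling. The ITAM list passed towards higher values (camera adjusted p = 0.0134; adjusted p = 0.436 with an estimated correlation), but not over genes with a mean TPM of at least 5 (camera adjusted p = 0.0595). ITAM list counts, higher and lower, were 8 and 1 without Plcg2+/+ 1, 8 and 1 without Plcg2-/- 1 and 9 and 1 without Plcg2-/- 3.

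Downstream of phospholipase C, calcium genes moved both ways. Itpr1, an inositol trisphosphate receptor gene, rose by 1.75 on the log2 scale, Rasgrp4 by 2.47 and Nfatc2 by 1.45, while Itpr3 fell by 1.70 (highest limma adjusted p = 0.00414). Of 26 tested calcium and protein kinase C genes, 10 were higher and 3 lower, against 11 and 3 adjusted over the list alone and 8 and 3 after median-of-ratios scaling. They did not pass as a list (camera adjusted p = 0.411), except with no filter on low values (camera adjusted p = 0.0128). Calcium and protein kinase C counts, higher and lower, were 5 and 2 without Plcg2+/+ 1, 4 and 1 without Plcg2-/- 1 and 5 and 2 without Plcg2-/- 3. The phosphatase gene Synj1 and the kinase gene Pip4k2a, both of phosphoinositide turnover, rose by 1.19 and 1.06 on the log2 scale. Of 31 tested phosphoinositide and diacylglycerol genes, 7 were higher and 2 lower, against 9 and 3 adjusted over the list alone and 4 and 4 after median-of-ratios scaling. Phosphoinositide and diacylglycerol genes counted 9 higher and 1 lower with the replicate block. That list did not pass (camera adjusted p = 0.810). Phosphoinositide counts, higher and lower, were 4 and 0 without Plcg2+/+ 1, 5 and 1 without Plcg2+/+ 2, 5 and 1 without Plcg2+/+ 3, 3 and 0 without Plcg2-/- 1, 8 and 1 without Plcg2-/- 2 and 4 and 1 without Plcg2-/- 3.

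Of arachidonoyl remodelling genes, a list that holds acyltransferases, phospholipases, desaturases and other fatty acid enzymes, 4 of 18 fell and 2 rose. Acsl3 and Lpcat1 fell by 0.75 and 0.61 on the log2 scale, while Mboat1 and Lpcat2 rose by 1.06 and 0.55 (limma adjusted p = 0.0119, 0.0205, 0.0174 and 0.0307). Of 18 tested arachidonoyl remodelling genes, 2 were higher and 4 lower, against 2 and 4 adjusted over the list alone and 1 and 6 after median-of-ratios scaling. The list passed towards lower values (camera adjusted p = 0.00587; adjusted p = 0.436 with an estimated correlation). Arachidonoyl remodelling counts, higher and lower, were 0 and 2 without Plcg2+/+ 1, 1 and 1 without Plcg2+/+ 2, 0 and 0 without Plcg2-/- 1, 1 and 2 without Plcg2-/- 2 and 0 and 1 without Plcg2-/- 3. Acsl3 had a limma adjusted p of 0.063 without Plcg2-/- 1, Lpcat1 one of 0.0642 without Plcg2+/+ 2, 0.0911 without Plcg2-/- 1 and 0.077 without Plcg2-/- 3, and Mboat1 one of 0.0686 without Plcg2+/+ 1, 0.079 without Plcg2-/- 1 and 0.0692 without Plcg2-/- 3. Lpcat2 had one of 0.108 after median-of-ratios scaling, 0.092 without Plcg2+/+ 1, 0.0748 without Plcg2+/+ 2, 0.0836 without Plcg2-/- 1, 0.0708 without Plcg2-/- 2 and 0.0886 without Plcg2-/- 3. In the phospholipase C family, Plcl2 rose by 0.92 on the log2 scale and Plcg1 fell by 0.41 (limma adjusted p = 0.00357 and 0.0413). Of 7 tested phospholipase C genes, 1 were higher and 2 lower, against 1 and 2 adjusted over the list alone and 1 and 3 after median-of-ratios scaling. The family, which holds Plcg2 itself, passed towards lower values (camera adjusted p = 0.0432; adjusted p = 0.430 with an estimated correlation). Its camera adjusted p was 0.0607 after median-of-ratios scaling, 0.0509 after quantile normalization, 0.0922 with no filter on low values, 0.117 over genes with a mean TPM of at least 5, 0.0568 without Plcg2+/+ 1, 0.0582 without Plcg2-/- 2, 0.0605 without Plcg2-/- 3 and 0.0633 without both libraries numbered 1. Rescaling without mitochondrially encoded genes gave 0.0963, scaling without the 100 most abundant genes 0.0695, and the replicate block with median-of-ratios scaling 0.075. Without any 1 library, phospholipase C counts were 1 and 1, since the limma adjusted p of Plcg1 was 0.119 without Plcg2+/+ 1, 0.112 without Plcg2+/+ 2, 0.0575 without Plcg2+/+ 3, 0.128 without Plcg2-/- 1, 0.0742 without Plcg2-/- 2 and 0.116 without Plcg2-/- 3. With the replicate block that of Plcg1 was 0.0514.

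Of interferon response genes, 34 of 35 rose. Mx1, an antiviral GTPase gene, rose from 9.58 ± 1.49 to 142 ± 25.2 TPM, Ifit3 from 55.5 ± 14.9 to 669 ± 149.6 and Cmpk2 from 15.95 ± 2.54 to 96.8 ± 17.4 (SD, n = 3 each; highest limma adjusted p = 0.000717). Of 35 tested type I interferon response genes, 34 were higher and 0 lower, against 35 and 0 adjusted over the list alone and 34 and 0 after median-of-ratios scaling. Their median log2 fold change was 1.95 above that of all tested genes. The list passed towards higher values (camera adjusted p = 7.36e-21; adjusted p = 0.430 with an estimated correlation). Of the genes of MHC class II, which presents antigen to T cells, 7 of 12 rose. H2-Eb1 rose from 14.9 ± 5.10 to 138 ± 46.7 TPM, H2-Ab1 from 23.9 ± 4.05 to 169 ± 53.4, H2-Aa from 22.8 ± 5.47 to 160.2 ± 50.6 and the invariant chain gene Cd74 from 207 ± 33.0 to 961 ± 254 (highest limma adjusted p = 0.00189). Of 12 tested MHC class II genes, 7 were higher and 0 lower, against 10 and 0 adjusted over the list alone and 6 and 0 after median-of-ratios scaling. MHC class II genes passed towards higher values (camera adjusted p = 0.000972; adjusted p = 0.436 with an estimated correlation). In the same libraries Pf4 and Vcan, markers of border macrophages and monocytes, rose from 29.2 ± 6.88 to 122 ± 17.8 and from 1.35 ± 0.524 to 18.4 ± 6.38 TPM.

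Of inflammatory genes, 11 of 28 rose and 1 fell. The chemokine gene Ccl7 rose by 3.87 on the log2 scale and the costimulatory receptor gene Cd40 by 2.37, while Tnfaip3, which encodes an inhibitor of NF-kB signalling, fell by 1.11 (highest limma adjusted p = 0.00482). Of 28 tested inflammatory cytokine and NF-kB genes, 11 were higher and 1 lower, against 13 and 1 adjusted over the list alone and 6 and 1 after median-of-ratios scaling. They passed towards higher values (camera adjusted p = 0.0387; adjusted p = 0.719 with an estimated correlation). That call was lost with the replicate block (camera adjusted p = 0.0566), with sample weights (0.0831), over genes with a mean TPM of at least 5 (0.117) and without Plcg2-/- 2 (0.249). Inflammatory counts, higher and lower, were 7 and 1 without Plcg2+/+ 1, 5 and 1 without Plcg2-/- 1 and 7 and 1 without Plcg2-/- 2. Of alternative activation genes, the lectin genes Clec10a and Mgl2 rose by 3.07 and 1.88 on the log2 scale and the signalling inhibitor gene Cish by 1.25 (limma adjusted p of Cish = 0.0389, 0.0570 after median-of-ratios scaling, 0.122 without Plcg2+/+ 1, 0.126 without Plcg2+/+ 2, 0.142 without Plcg2-/- 1 and 0.126 without Plcg2-/- 3). The mannose receptor gene Mrc1 stood at 206 ± 51.0 TPM in Plcg2+/+ and 378 ± 103 TPM in Plcg2-/- (limma adjusted p = 0.0599, 0.00707 with the replicate block, 0.0378 without Plcg2-/- 2). Of 11 tested alternative activation genes, 3 were higher and 0 lower, against 4 and 0 adjusted over the list alone and 2 and 0 after median-of-ratios scaling. Alternative activation genes counted 5 higher and 0 lower with the replicate block. As a list these did not pass (camera adjusted p = 0.237), except with no filter on low values (camera adjusted p = 0.0473), after scaling without the 100 most abundant genes (0.0371) and with the replicate block and median-of-ratios scaling together (0.0345).

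Genes of disease-associated microglia, the lipid-handling state described around amyloid plaques, were among the strongest decreases. Lpl, lipoprotein lipase, fell from 3343 ± 740.3 to 368 ± 62.0 TPM and Ctsl, a lysosomal protease gene, from 2585 ± 739 to 521 ± 47.8 (SD, n = 3 each; limma adjusted p = 0.000717 and 0.00151), beside Spp1, Itgax and Mamdc2. Ch25h, cholesterol 25-hydroxylase, rose by 2.26 on the log2 scale (limma adjusted p = 0.00953). Spp1, Mmp12, Mfge8 and Lpl, summed after their values were seen, took 4.74 ± 0.984% (SD, n = 3) of all TPM in Plcg2+/+ and 0.349 ± 0.13% (SD, n = 3) in Plcg2-/- libraries. Of monocyte, border macrophage and dendritic markers, 4 of 12 rose and 1, Fn1, fell in the same libraries. Of 30 tested disease-associated genes, 3 were higher and 11 lower, against 4 and 11 adjusted over the list alone and 1 and 11 after median-of-ratios scaling. They passed towards lower values (camera adjusted p = 0.000205; adjusted p = 0.241 with an estimated correlation), but not after quantile normalization (camera adjusted p = 0.158). Disease-associated counts, higher and lower, were 1 and 6 without Plcg2+/+ 1, 2 and 7 without Plcg2+/+ 2, 5 and 9 without Plcg2+/+ 3, 1 and 7 without Plcg2-/- 1, 1 and 8 without Plcg2-/- 2 and 2 and 6 without Plcg2-/- 3.

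Of matrix and protease genes of macrophages, 8 of 18 fell and 1 rose. The collagenase gene Mmp13 fell by 2.40, Adamts1 by 3.16 and the fibronectin gene Fn1 by 3.47 on the log2 scale (highest limma adjusted p = 0.00141). Of 18 tested matrix and protease genes, 1 were higher and 8 lower, against 2 and 9 adjusted over the list alone and 1 and 9 after median-of-ratios scaling. Matrix and protease genes counted 2 higher and 9 lower with the replicate block. Matrix and protease genes passed towards lower values (camera adjusted p = 6.44e-05; adjusted p = 0.241 with an estimated correlation). Matrix and protease counts, higher and lower, were 2 and 9 without Plcg2-/- 2. In the lysosome, the protease gene Ctsk fell by 1.59 and the glucuronidase gene Gusb by 0.75 on the log2 scale (limma adjusted p = 0.00637 and 0.0106). Of 42 tested lysosome genes, 3 were higher and 6 lower, against 4 and 7 adjusted over the list alone and 1 and 9 after median-of-ratios scaling. Lysosome genes counted 5 higher and 7 lower with the replicate block. Lysosome genes passed towards lower values (camera adjusted p = 0.00199; adjusted p = 0.436 with an estimated correlation). Lysosome counts, higher and lower, were 0 and 2 without Plcg2+/+ 1, 2 and 3 without Plcg2+/+ 2, 0 and 2 without Plcg2-/- 1 and 1 and 4 without Plcg2-/- 3. Gusb had a limma adjusted p of 0.0508 without Plcg2+/+ 1 and 0.0556 without Plcg2-/- 1.

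Phagocytic and scavenger receptor genes split. The integrin gene Itgam fell from 429 ± 76.5 to 81.8 ± 15.9 TPM, the fatty acid scavenger receptor gene Cd36 from 722 ± 222 to 107 ± 23.9 and Cd14 from 287 ± 25.2 to 128 ± 21 (SD, n = 3 each; highest limma adjusted p = 0.00342). Of 23 tested phagocytic and scavenger receptor genes, 6 were higher and 7 lower, against 8 and 9 adjusted over the list alone and 6 and 8 after median-of-ratios scaling. Phagocytic genes did not pass (camera adjusted p = 0.0809), except over genes with a mean TPM of at least 5 (camera adjusted p = 0.00981). Phagocytic counts, higher and lower, were 2 and 7 without Plcg2+/+ 1, 2 and 7 without Plcg2-/- 1 and 1 and 6 without Plcg2-/- 3. Homeostatic microglia genes split too. Fcrls and P2ry13 rose by 3.28 and 2.34 on the log2 scale, Rnase4 by 1.34, and Olfml3 fell by 3.16 (highest limma adjusted p = 0.00688). Of 18 tested homeostatic genes, 4 were higher and 2 lower, against 6 and 3 adjusted over the list alone and 4 and 3 after median-of-ratios scaling. Homeostatic genes counted 7 higher and 4 lower with the replicate block. Homeostatic genes did not pass as a list (camera adjusted p = 0.810). The list holds 25 genes, and members with a mean TPM under 1 were not tested. Among these, Tmem119 stood at 0.917 TPM in Plcg2+/+ and 0.279 TPM in Plcg2-/-. Sall1 stood at 0.256 and 0.206 TPM and Siglech at 0 and 0.0222 TPM, in the same order. Sall3, Slc2a5, Upk1b and Smad3 were not tested either, so the split does not cover these genes. Homeostatic counts, higher and lower, were 3 and 1 without Plcg2+/+ 1, 3 and 1 without Plcg2-/- 1 and 3 and 1 without Plcg2-/- 3. The complement genes C4b and Cfp, properdin, rose by 1.92 and 1.3 on the log2 scale. Of 16 tested complement genes, 3 were higher and 2 lower, against 5 and 2 adjusted over the list alone and 2 and 2 after median-of-ratios scaling. Complement genes counted 6 higher and 2 lower with the replicate block. Itgax and Itgam were the lower ones, and the list did not pass (camera adjusted p = 0.735).

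**Figure D2:**
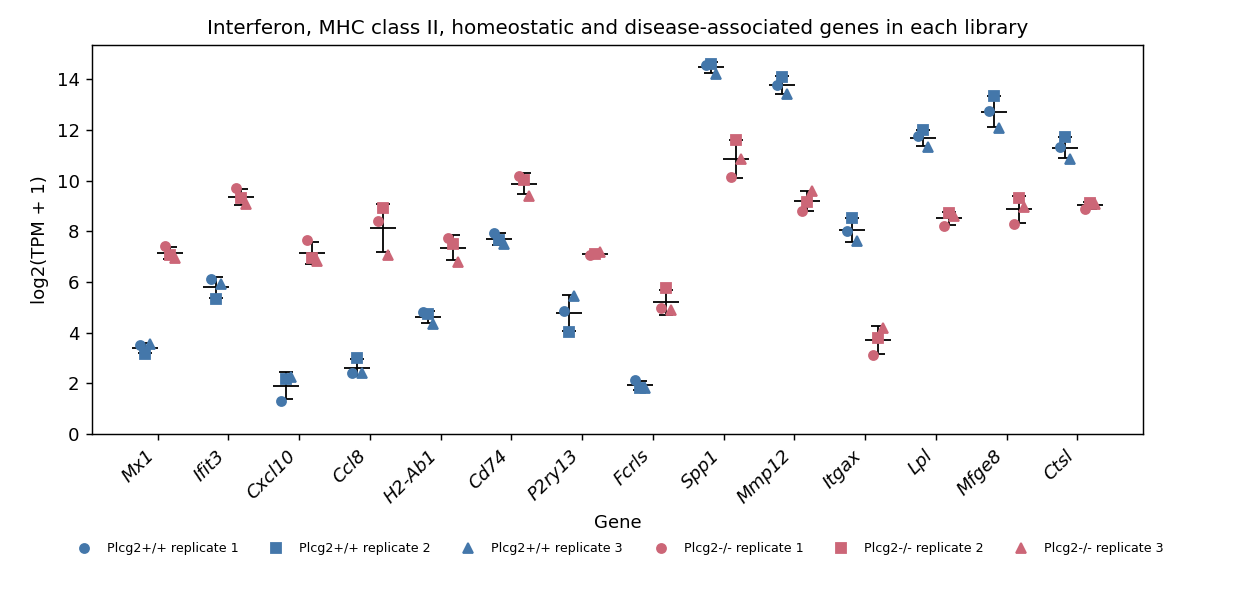
Log2(TPM + 1) of 14 genes of the interferon, MHC class II, homeostatic, disease-associated and matrix groups in each library, where symbols are single libraries, the black bar is the mean of 3 and whiskers are ± 1 SD. The Plcg2-/- libraries lie above all Plcg2+/+ libraries from Mx1 to Fcrls and below them from Spp1 to Ctsl.

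Of immediate early genes, which respond within minutes to receptor signals, 5 of 23 fell and 1 rose. Fos fell from 20.6 ± 0.405 to 6.69 ± 0.788 TPM, Egr2 from 59.1 ± 12.4 to 9.45 ± 2.12 and Dusp4 from 4.97 ± 1.65 to 0.366 ± 0.215 (SD, n = 3 each; highest limma adjusted p = 0.00390). Of 23 tested immediate early genes, 1 were higher and 5 lower, against 1 and 6 adjusted over the list alone and 0 and 7 after median-of-ratios scaling. Immediate early genes counted 3 higher and 7 lower with the replicate block. The list passed towards lower values (camera adjusted p = 0.00136; adjusted p = 0.241 with an estimated correlation). Immediate early counts, higher and lower, were 0 and 4 without Plcg2+/+ 1, 0 and 5 without Plcg2+/+ 2, 2 and 6 without Plcg2+/+ 3, 0 and 3 without Plcg2-/- 1 and 0 and 5 without Plcg2-/- 3. Growth factor genes moved both ways. The cytokine receptor subunit gene Csf2rb2 fell from 209 ± 54.4 to 70.3 ± 6.78 TPM, whereas Csf3r rose from 19.9 ± 2.80 to 58.7 ± 10.5. The kinase gene Jak2 rose from 11.4 ± 1.32 to 27.3 ± 4.14 TPM and the signalling inhibitor gene Socs1 from 1.38 ± 0.254 to 6.24 ± 1.73 (highest limma adjusted p of the 4 genes = 0.00556). Of 18 tested GM-CSF and M-CSF signalling genes, 6 were higher and 5 lower, against 7 and 6 adjusted over the list alone and 3 and 6 after median-of-ratios scaling. GM-CSF and M-CSF genes did not pass (camera adjusted p = 0.859). GM-CSF and M-CSF counts, higher and lower, were 3 and 1 without Plcg2+/+ 1, 3 and 2 without Plcg2+/+ 2, 6 and 3 without Plcg2+/+ 3, 3 and 2 without Plcg2-/- 1 and 3 and 3 without Plcg2-/- 3.

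Of lipid metabolism genes, Hilpda and the triglyceride synthesis gene Dgat1 fell by 1.28 and 1.44 on the log2 scale. Of 26 tested fatty acid and lipid droplet genes, 4 were higher and 3 lower, against 4 and 4 adjusted over the list alone and 3 and 4 after median-of-ratios scaling. Fatty acid genes did not pass (camera adjusted p = 0.371). Fatty acid counts, higher and lower, were 2 and 3 without Plcg2+/+ 1, 2 and 3 without Plcg2+/+ 2, 2 and 3 without Plcg2-/- 1 and 2 and 4 without Plcg2-/- 3. Of 20 tested cholesterol export genes, 2 were higher and 1 lower, against 1 and 1 adjusted over the list alone and 1 and 4 after median-of-ratios scaling. Cholesterol export genes counted 1 higher and 2 lower with the replicate block. Cholesterol export genes did not pass (camera adjusted p = 0.0681), except with the replicate block (camera adjusted p = 0.0446), after quantile normalization (0.0459), over genes with a mean TPM of at least 5 (0.0211), with the replicate block and median-of-ratios scaling together (0.0345) and without Plcg2+/+ 1 (0.0401). Cholesterol export counts, higher and lower, were 1 and 0 without Plcg2+/+ 1, 1 and 0 without Plcg2+/+ 2, 2 and 3 without Plcg2+/+ 3, 1 and 0 without Plcg2-/- 1, 1 and 0 without Plcg2-/- 2 and 1 and 0 without Plcg2-/- 3. Of 24 tested cholesterol synthesis genes, 0 were higher and 1 lower, against 0 and 0 adjusted over the list alone and 0 and 1 after median-of-ratios scaling. Cholesterol synthesis genes counted 0 higher and 2 lower with the replicate block. That 1 gene was Dhcr7 (limma adjusted p = 0.0257, 0.0657 without Plcg2+/+ 1, 0.0887 without Plcg2+/+ 2, 0.0564 without Plcg2+/+ 3 and 0.0762 without Plcg2-/- 1). Cholesterol synthesis genes did not pass (camera adjusted p = 0.0809), except over genes with a mean TPM of at least 5 (camera adjusted p = 0.0275) and with 0.0176 without Plcg2+/+ 2, 0.00795 without Plcg2-/- 1, 0.00525 without Plcg2-/- 3 and 0.00632 without both libraries numbered 1. Cholesterol synthesis counts, higher and lower, were 0 and 0 without Plcg2+/+ 1, 0 and 0 without Plcg2+/+ 2, 0 and 0 without Plcg2+/+ 3, 0 and 0 without Plcg2-/- 1 and 1 and 1 without Plcg2-/- 2. The glucose transporter gene Slc2a1 fell by 1.40 on the log2 scale. Of 23 tested glycolysis and hypoxia genes, 0 were higher and 3 lower, against 0 and 2 adjusted over the list alone and 0 and 5 after median-of-ratios scaling. Glycolysis and hypoxia genes counted 2 higher and 2 lower with the replicate block. Glycolysis genes did not pass (camera adjusted p = 0.0851), except after median-of-ratios scaling (0.0256), quantile normalization (0.0144), over genes with a mean TPM of at least 5 (0.0269), without Plcg2+/+ 1 (0.0377) and without Plcg2-/- 1 (0.0388). Glycolysis genes also passed without mitochondrially encoded genes (camera adjusted p = 0.0389), without the 100 most abundant genes (0.0198), with the replicate block and median-of-ratios scaling together (0.0345) and without both libraries numbered 1 (0.0153). Glycolysis counts, higher and lower, were 0 and 1 without Plcg2+/+ 2, 1 and 2 without Plcg2+/+ 3 and 0 and 1 without Plcg2-/- 1.

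In the cell cycle list, 1 of 38 genes fell. Of 38 tested cell cycle genes, 0 were higher and 1 lower, against 0 and 0 adjusted over the list alone and 0 and 2 after median-of-ratios scaling. Cell cycle genes counted 2 higher and 5 lower with the replicate block. That 1 gene was Cenpa, a centromere histone (limma adjusted p = 0.0411, 0.115 without Plcg2+/+ 1, 0.0935 without Plcg2+/+ 2, 0.091 without Plcg2+/+ 3, 0.147 without Plcg2-/- 1 and 0.104 without Plcg2-/- 2). Cell cycle genes passed towards lower values (camera adjusted p = 0.00145; adjusted p = 0.719 with an estimated correlation), but not with sample weights (camera adjusted p = 0.0718). Cell cycle counts, higher and lower, were 0 and 0 without Plcg2+/+ 1, 0 and 0 without Plcg2+/+ 2, 1 and 0 without Plcg2+/+ 3, 0 and 0 without Plcg2-/- 1, 0 and 0 without Plcg2-/- 2 and 0 and 2 without Plcg2-/- 3. The stress regulators Xbp1 and Atf5 rose by 0.78 and 0.67 on the log2 scale. Of 23 tested stress response genes, 5 were higher and 1 lower, against 6 and 1 adjusted over the list alone and 5 and 3 after median-of-ratios scaling. They did not pass as a list (camera adjusted p = 0.988). Stress response counts, higher and lower, were 3 and 0 without Plcg2-/- 1. Of the mitochondrially encoded genes, 11 of 13 fell. The oxidase subunit gene mt-Co3 fell by 1.21 and the NADH dehydrogenase gene mt-Nd1 by 1.23 on the log2 scale (limma adjusted p = 0.0195 and 0.0230). Of 13 tested mitochondrially encoded genes, 0 were higher and 11 lower, against 0 and 13 adjusted over the list alone and 0 and 12 after median-of-ratios scaling. Mitochondrially encoded genes passed towards lower values (camera adjusted p = 9.18e-10; adjusted p = 0.436 with an estimated correlation). The mitochondrial share was 13.6 to 17.3% in the Plcg2+/+ and 5.00 to 8.68% in the Plcg2-/- libraries. Fewer single genes of this group were called with fewer samples in the fit: counts, higher and lower, were 0 and 0 without Plcg2+/+ 1, 0 and 0 without Plcg2+/+ 2, 0 and 0 without Plcg2-/- 1, 0 and 2 without Plcg2-/- 2 and 0 and 3 without Plcg2-/- 3. mt-Co3 had a limma adjusted p of 0.0753 without Plcg2+/+ 1, 0.0583 without Plcg2+/+ 2, 0.079 without Plcg2-/- 1 and 0.0552 without Plcg2-/- 3, and mt-Nd1 one of 0.0829 without Plcg2+/+ 1, 0.0737 without Plcg2+/+ 2 and 0.0636 without Plcg2-/- 1. Of 34 tested ribosomal protein genes, 0 were higher and 0 lower, against 0 and 0 adjusted over the list alone and 0 and 0 after median-of-ratios scaling. Of these, Rplp1 came nearest, at 0.66 on the log2 scale (limma adjusted p = 0.0586, 0.0438 without Plcg2+/+ 3). Ribosomal protein genes passed towards higher values (camera adjusted p = 0.00791; adjusted p = 0.753 with an estimated correlation), but not without Plcg2-/- 2 (camera adjusted p = 0.0688). Ribosomal protein counts, higher and lower, were 13 and 0 without Plcg2+/+ 3.

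**Figure D3:**
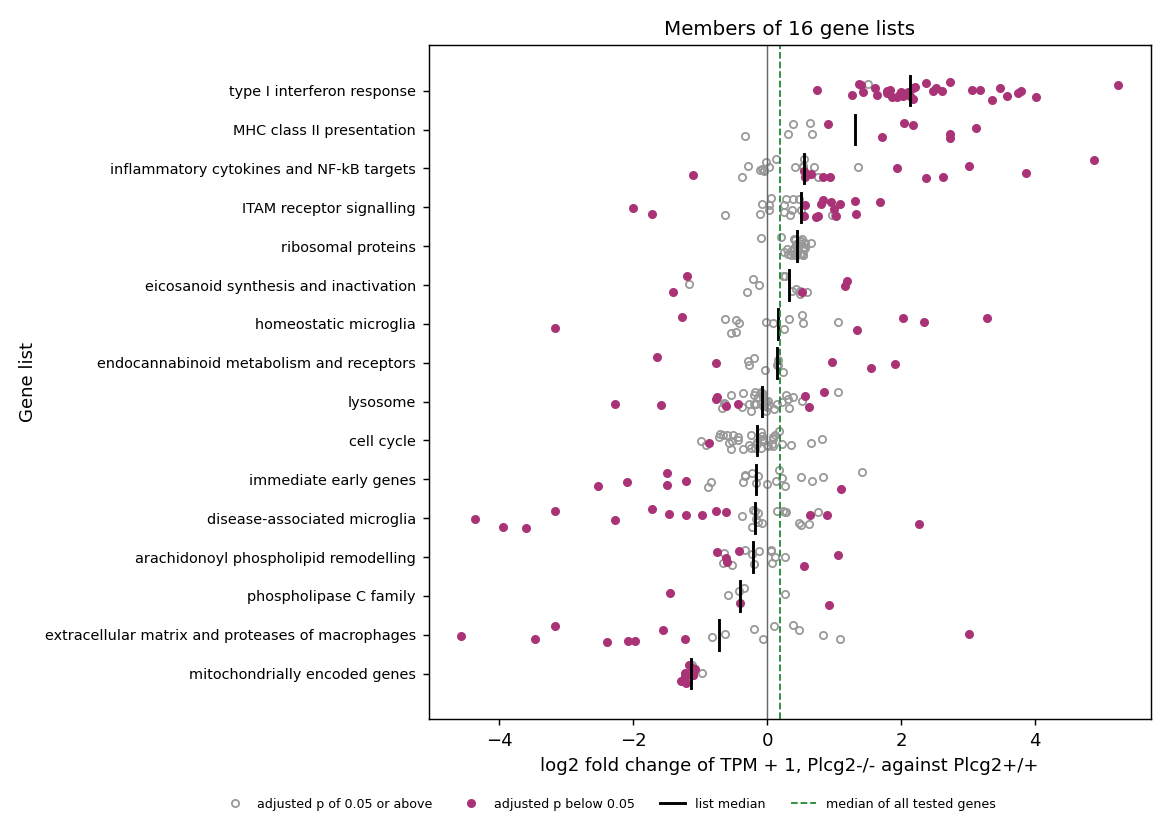
Log2 fold changes of single genes, Plcg2-/- over Plcg2+/+, in the 13 lists that passed camera with a preset correlation and in the endocannabinoid, eicosanoid synthesis and homeostatic lists. Filled points passed limma at an adjusted p below 0.05, black bars are list medians and the dashed line is the median of all tested genes, 0.19; all 35 interferon genes lie right of 0 and all 13 mitochondrially encoded genes left of it.

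Markers of other cells that such cultures could hold were measured beside these groups. Pf4 and Vcan, of border macrophages and monocytes, rose from 29.2 ± 6.88 to 122 ± 17.8 and from 1.35 ± 0.524 to 18.4 ± 6.38 TPM, and Cbr2 from 1.71 ± 1.96 to 8.72 ± 1.42 TPM (SD, n = 3 each; limma adjusted p = 0.00159, 0.00162 and 0.0247). Of 12 tested monocyte, border macrophage and dendritic markers, 4 were higher and 1 lower, against 6 and 1 adjusted over the list alone and 3 and 1 after median-of-ratios scaling. They did not pass as a list (camera adjusted p = 0.314), except with the replicate block and median-of-ratios scaling together (camera adjusted p = 0.0336) and after scaling without the 100 most abundant genes (0.0455). In that list 6 of the 20 listed genes stand in another list. Monocyte and border macrophage counts, higher and lower, were 2 and 1 without Plcg2+/+ 1, 2 and 1 without Plcg2-/- 1 and 2 and 1 without Plcg2-/- 3. Cbr2 had a limma adjusted p of 0.0893 without Plcg2+/+ 1, 0.0616 without Plcg2+/+ 2, 0.101 without Plcg2-/- 1, 0.0539 without Plcg2-/- 2 and 0.0894 without Plcg2-/- 3. Of 7 tested astrocyte markers, 1 were higher and 0 lower, against 1 and 0 adjusted over the list alone and 1 and 0 after median-of-ratios scaling. The higher one was Aldh1l1, a folate enzyme gene, at 1.13 on the log2 scale (limma adjusted p = 0.0282, 0.0938 without Plcg2+/+ 1, 0.0929 without Plcg2+/+ 2, 0.106 without Plcg2-/- 1 and 0.0941 without Plcg2-/- 3). Of 5 tested fibroblast and meningeal markers, 1 were higher and 2 lower, against 1 and 2 adjusted over the list alone and 0 and 2 after median-of-ratios scaling. Lox fell by 2.85 on the log2 scale and Igfbp4 rose by 1.74 (limma adjusted p = 0.00141 and 0.0358). Fibroblast counts, higher and lower, were 0 and 1 without Plcg2+/+ 1, 0 and 2 without Plcg2+/+ 3, 0 and 1 without Plcg2-/- 1, 0 and 1 without Plcg2-/- 2 and 0 and 1 without Plcg2-/- 3. Igfbp4 had a limma adjusted p of 0.0758 after median-of-ratios scaling, 0.116 without Plcg2+/+ 1, 0.0825 without Plcg2+/+ 3, 0.0855 without Plcg2-/- 1, 0.095 without Plcg2-/- 2 and 0.101 without Plcg2-/- 3. Of 10 tested oligodendrocyte lineage markers, 1 were higher and 1 lower, against 1 and 1 adjusted over the list alone and 1 and 1 after median-of-ratios scaling. Cspg4 fell from 9.62 ± 3.24 to 0.471 ± 0.309 TPM and Cnp rose from 15.3 ± 2.27 to 34.4 ± 2.41. Of 5 tested neuron markers, 0 were higher and 0 lower, against 0 and 0 adjusted over the list alone and 0 and 1 after median-of-ratios scaling. Neuron markers counted 0 higher and 1 lower with the replicate block. Astrocyte, fibroblast, oligodendrocyte and neuron lists did not pass (camera adjusted p = 0.493, 0.371, 0.298 and 0.120). Without Plcg2+/+ 1 the camera adjusted p was 0.0377 for oligodendrocyte lineage markers and 0.00438 for neuron markers, and without both libraries numbered 1 it was 0.00632 for neuron markers. The endothelial, lymphocyte, granulocyte and histone lists had too few tested members for camera. Of 3 tested endothelial markers, 1 were higher and 1 lower, against 1 and 1 adjusted over the list alone. These were Kdr and Flt1. The 1 lymphocyte marker tested, Cd4, was higher, and the 1 granulocyte marker and 4 replication-dependent histones tested had 0 calls, or 1 and 0 for histones with the replicate block.

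Genes near Plcg2 and the sex of the libraries were examined as well. Maf, a macrophage transcription factor gene, rose from 17.1 ± 3.99 to 76.1 ± 15.6 TPM and the replication gene Gins2 fell from 8.48 ± 1.43 to 4.63 ± 0.467 (SD, n = 3 each; limma adjusted p = 0.00177 and 0.0194). Of 26 tested genes flanking Plcg2 on chromosome 8, 5 were higher and 1 lower, against 6 and 1 adjusted over the list alone and 1 and 1 after median-of-ratios scaling. Flanking genes did not pass (camera adjusted p = 0.371). Flanking gene counts, higher and lower, were 1 and 1 without Plcg2+/+ 1, 1 and 0 without Plcg2+/+ 2, 3 and 1 without Plcg2+/+ 3, 1 and 0 without Plcg2-/- 1, 3 and 1 without Plcg2-/- 2 and 1 and 0 without Plcg2-/- 3. Gins2 had a limma adjusted p of 0.0534 without Plcg2+/+ 2, 0.0859 without Plcg2-/- 1 and 0.0621 without Plcg2-/- 3. Within 5 Mb of Plcg2, 12 of 61 genes were called, 19.7%, against 20.9% elsewhere (two-sided Fisher's exact p = 1). Sex-linked transcripts differed within genotypes and in part between them. In Plcg2+/+ 1, 2 and 3 the 4 Y-linked genes summed to 0.371, 107 and 112 TPM. In Plcg2-/- 1, 2 and 3 they summed to 58.6, 0.783 and 0.994 TPM. Xist, expressed from the inactive X chromosome, stood at 50.5, 0.747 and 1.02 TPM and at 18.4, 49.4 and 40.3 TPM in the same order. Plcg2-/- 1 thus held both Xist and Y-linked transcripts and cannot be assigned to one sex. Whether pups were pooled is not given in the sources used here. The Y-linked mean was 73.0 TPM in Plcg2+/+ and 20.1 TPM in Plcg2-/- (two-sided exact permutation p = 0.4). The libraries numbered 2 and 3 had Y-linked transcripts in Plcg2+/+ and Xist in Plcg2-/-. Within these pairs, and without both libraries numbered 1, sex and genotype cannot be told apart. Of 5 tested X-inactivation and Y-linked genes, 0 were higher and 0 lower, against 0 and 0 adjusted over the list alone and 0 and 0 after median-of-ratios scaling. Sex-linked genes did not pass (camera adjusted p = 0.269), except without both libraries numbered 1 (camera adjusted p = 8.45e-05), and without Plcg2+/+ 1 the counts were 1 and 0.

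In all, 13 of 35 lists passed camera with a preset correlation of 0.01, 5 towards higher and 8 towards lower values. Splits of the libraries that mix the genotypes passed up to 12 lists in the same test. Some lists share members, so their calls are not independent results. Of the listed genes, 16 of 30 disease-associated, 10 of 42 lysosome and 3 of 22 matrix and protease genes stand in another list. With an estimated correlation 0 of 35 passed camera, the lowest adjusted p being 0.241, and 3 had an unadjusted p below 0.05. That setting also rests on the few residual degrees of freedom, 4 here, so a lost call does not measure correlation alone. The matrix and protease list had an estimated correlation of 0.00859, near the preset 0.01. Its unadjusted camera p was 5.52e-06 with the preset and 0.0101 with the estimate. The directional fry test, which asks whether members move one way without comparing them with other genes, passed 11. The camera test pointed down although median and mean were above 0 in the endocannabinoid, eicosanoid synthesis, eicosanoid receptor, phosphoinositide, homeostatic, complement and GM-CSF lists. Of these, the eicosanoid synthesis, complement and GM-CSF medians also lay above that of all tested genes, by 0.13, 0.21 and 0.27. In the phagocytic, fatty acid, glycolysis and fibroblast lists the median was above 0 while mean and test pointed down. The astrocyte median was below 0 with a mean above it, and the stress list lay below the median of all genes with a test that pointed up.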

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

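Rescaling without mitochondrially encoded genes, scaling without the 100 most abundant genes, the replicate block with median-of-ratios scaling and leaving out both libraries numbered 1 were chosen after the data were seen. The rule for named genes took 127 genes past the threshold besides Plcg2, of which 92 stayed past it whichever single library was left out and 101 under every other planned setting. Of the 111 named in the text these numbers were 89 and 95. Exceptions under the latter settings were Aldh1l1, Cbr2, Cenpa, Cish, Cysltr1, Dhcr7, Gins2, Igfbp4, Lpcat1, Lpcat2, mt-Co3, mt-Nd1, Naaa, Plcg1, Ptges3 and Ptgs1. With the Y-linked covariate 13 of them lost their call, all but Aldh1l1, mt-Co3 and mt-Nd1. For Lpcat1 and Ptgs1 it was the only such setting. That fit has 3 residual degrees of freedom instead of 4, so a lost call does not measure sex alone. No called gene changed sign in any setting run. The Plcg2 log2 fold change lay between -1.70 and -1.33 and kept its call, except without both libraries numbered 1 (-1.46, limma adjusted p = 0.0697), where 71 genes were higher and 35 lower with 4 libraries left, 13 of the interferon genes among the higher. Lists past the threshold by directional tests numbered 10 to 16, apart from 0 with an estimated correlation, and 29 passed the mixed fry test, which asks whether members change in either direction.

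Higher counts were 1226 with no filter on low values, 975 with median-of-ratios scaling, 959 with quantile normalization (1031 lower), 3282 with sample weights, and 941 higher and 411 lower with the Y-linked level as a covariate, which costs 1 degree of freedom. Rescaling without mitochondrially encoded genes gave 1222 higher, scaling without the 100 most abundant genes 870 higher and 1123 lower, and the replicate block with median-of-ratios scaling 1104 higher and 1127 lower; these scalings centre the genes differently. A minimum of 2-fold gave 593 higher and 357 lower, and at an adjusted p below 0.1 the genes higher in Plcg2-/- numbered 3096. Leaving out 1 library gave 559 to 2106 higher and 276 to 644 lower genes, with fewer samples in the fit. The replicate block gave 2483 higher and 815 lower, 13 lists and a Plcg2 log2 fold change of -1.45, and changed no call of a named gene or list beyond those given in the report.

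List direction below is the sign of the list median relative to all genes, a definition adopted after results under the direction of the camera test had been seen. By the median 30 of 730 pairs of list and setting changed sign, and by the camera direction 41, in 9 lists; 0 of these 41 were in lists that had passed. For the values that follow the cause was not tested. Relative to all genes, the list median was 0.11 for endocannabinoid metabolism and receptors, 0.089 for phosphoinositide and diacylglycerol turnover, 0.037 for fatty acid uptake, lipid droplets and oxidation, 0.16 for integrated and unfolded protein stress and 0.031 for homeostatic microglia with no filter on low values. It was 0.0997 for homeostatic microglia and -0.11 for phagocytic and scavenger receptors (camera adjusted p = 0.00981) with a mean TPM of at least 5, and -0.066 for phagocytic and scavenger receptors with quantile normalization. With sample weights it was 0.041 for homeostatic microglia, 0.016 for cholesterol synthesis, 0.041 for integrated and unfolded protein stress and 0.039 for X-inactivation and Y-linked genes; it was 0.0021 for homeostatic microglia with the Y-linked covariate, 0.049 for homeostatic microglia without mitochondrially encoded genes, and 0.040 for integrated and unfolded protein stress without both libraries numbered 1. The log2 fold change of Mgll was -0.052 with median-of-ratios scaling, with or without the replicate block, -0.11 with quantile normalization and -0.096 without the 100 most abundant genes; that of Cnr2 was 0.071 with sample weights and 0.033 with the Y-linked covariate. Over the settings that leave out 1 library, Mgll ranged from -0.020 to 0.26 and Cnr2 from -0.16 to 0.19, and relative list medians from -0.040 to 0.27 for eicosanoid synthesis and inactivation, -0.14 to 0.085 for homeostatic microglia, -0.47 to 0.095 for cholesterol synthesis, -0.21 to 0.0088 for fatty acid uptake, lipid droplets and oxidation, -0.10 to 0.10 for phagocytic and scavenger receptors, -0.026 to 0.39 for complement, -0.022 to 0.085 for integrated and unfolded protein stress, -0.61 to 0.046 for astrocyte markers, -0.45 to 0.087 for oligodendrocyte lineage markers and -0.021 to 0.31 for fibroblast and meningeal markers. Without read counts, the part of the spread that comes from depth could not be separated. In the simulation a log2 change of 0.5 was not recovered. It gave 136 calls, against 2643 in the real libraries, so its Benjamini-Hochberg cut-off was stricter. That result therefore sets no lower limit on the sizes called here.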

Other observations

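The tests of sex composition, of median-of-ratios scaling, of mitochondrially encoded transcripts, of the 100 most abundant genes and of a replacement of microglia were chosen after the results they bear on were seen, as were the gene families below.

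Some families grouped by the stem of their symbols rose, and some of their members also stand in the interferon list. Among 375 stems with at least 5 tested members, Gbp genes, which encode guanylate-binding proteins of cell-autonomous defence, had 9 of 10 members higher with a median log2 fold change of 2.97, the Ms4a stem 9 of 9 at 2.38, the Slfn stem 7 of 8 at 1.98 and the Oas stem 6 of 6 at 1.33 (camera adjusted p = 2.41e-05, 0.000134, 0.000561 and 0.00479; adjusted p = 0.976 with an estimated correlation for each). Toll-like receptor genes of the Tlr stem had 6 of 9 higher and none lower, at a median of 1.12, and poly(ADP-ribose) polymerase genes of the Parp stem 7 of 12 at 1.10 (camera adjusted p = 0.0447 and 0.0483; adjusted p = 0.976 with an estimated correlation for both). In all, 11 stems passed towards higher and 5 towards lower values. The latter were Snhg, of small nucleolar RNA host genes, with 2 lower and 0 higher of 14, Mmp with 3 lower and 1 higher of 7, Galnt with 5 lower and 2 higher of 13, Slc with 27 lower and 21 higher of 200, and Slc27a with 2 lower and 0 higher of 6 (camera adjusted p = 0.00297, 0.00989, 0.0148, 0.0190 and 0.0363; adjusted p = 0.976 with an estimated correlation for each). With an estimated correlation 0 stems passed camera and 4 had an unadjusted p below 0.05, and whether reads were shared between relatives was not tested.

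The rise of interferon response genes in Plcg2-/- libraries was set against 3 technical explanations. Sex-linked transcripts differed between libraries of one genotype and in part between the genotypes, and Plcg2-/- 1 held those of both sexes. With the Y-linked level as a covariate the list median was 2.13 on the log2 scale, the value without it being 2.13. After median-of-ratios scaling the list median was 1.92. That scaling uses 1 factor per library and moved the median of all tested genes only from 0.19 to -0.0045. It could not have removed the rise, so it does not test scaling. On deposited TPM the list median lay 1.95 above that of all tested genes, a gap that such a factor leaves nearly unchanged. The differences between libraries with the same number were 2.15, 2.36 and 1.97, so no single pair was the source. An effect of genotype may underlie the rise, as a hypothesis. Reads shared between relatives and a difference in culture between the genotypes were not tested, and the list's call was lost with an estimated correlation.

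The share of increases among the calls moved with the scale. After rescaling without mitochondrially encoded genes, 59.8% of the calls were increases, down from 74.6%, and after scaling without the 100 most abundant genes 43.7%. These rescalings moved all genes nearly alike, by a median of -0.124 and -0.242 on the log2 scale with median absolute deviations of 0.0108 and 0.0217, which by itself lowers the share, so they do not show whether abundant transcripts account for it. TPM values alone do not show whether the amount of RNA per cell differed.

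The fall of Spp1, Mmp12 and Itgax, beside 4 increases and 1 decrease, that of Fn1 (-3.47 on the log2 scale), among 12 monocyte, border macrophage and dendritic markers that did not pass as a list (camera adjusted p = 0.314; 0.0336 with the replicate block and median-of-ratios scaling together, and 0.0455 without the 100 most abundant genes), could reflect another macrophage type in place of microglia. The tested members of the homeostatic microglia list argue against that as the whole cause. Their median log2 fold change was 0.17 (median absolute deviation 0.99), while the smallest fall of the 3 genes was -3.60. Cells lost would take their transcripts with them. Tmem119, Sall1 and Siglech lay below the expression filter in these libraries and are not in that median. Sex composition did not account for the fall of the 3 genes, since with the Y-linked covariate the smallest fall was -3.81. A change of state within the microglia stays open as a hypothesis, and a partial admixture of such cells, which carry MHC class II, was not tested.

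Other groupings of the libraries were fitted in the same way. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The genotype split gave 2643 called genes and was the 1 split of 10 with as many. The highest of the others gave 3, and the highest of the other splits that part all 3 pairs gave 2. Each of the other splits mixes the genotypes in both groups, so a genotype difference widens their spread and lowers their calls. Their gene counts therefore do not show what libraries without a genotype difference would give. For lists past the threshold the genotype split gave 13 and was again the 1 split of 10 with as many. The highest of the others gave 12, with 0 genes called. The highest of the other splits that part all 3 pairs gave 10. The number of lists passed therefore sets the genotype split little apart from splits that mix the genotypes.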
